A study of Mus musculus with 10 samples.

How the data were processed

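Gene expression was measured in 10 samples of sorted mouse CD8 T cells, each on 1 single-colour Agilent array. Per the labels' protocols, the RNA of the sorted cells was turned into cDNA and amplified by a global PCR procedure made for small numbers of cells, and Cy3-labelled product was hybridised. The deposited scanner files hold intensity values made with Agilent Feature Extraction 10.5.1.1, per the file headers; the submitters' processing notes name the same program. The processed signal in these files is a background-subtracted spot intensity, deposited without any scaling between arrays, per the file headers. The authors also deposited a table of log2 values for the same arrays. Set against log2 processed signal, its columns correlated at 0.995 to 1.00 across probes and rose with it, so its scale was log2 and its direction that of the signal. Its column medians were 6.15, 6.13 and 6.10 for naive replicates 1 to 3, 6.10, 6.11, 6.09 and 6.12 for TIL replicates 1 to 4, and 6.12, 6.11 and 6.10 for AdP1A replicates 1 to 3. The centring was close to equal medians, and its exact method was not given in the sources used here. That table served as an alternative.

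Each array carried 62976 spots, of which 3671 were controls and were left out. Spots marked as outliers were removed, which left 96 probes without a value on at least 1 array, and no non-control spot was saturated on any array. Replicate spots of 432 probes were averaged. The main values were log2 processed signal minus the 75th percentile of each array over its 55681 non-control probes. A probe entered the tests if it was well above background on at least 3 arrays, which 40444 probes were. A gene was represented by its probe with the highest mean over all arrays, which gave 27424 tested features, 17259 of them with a gene symbol. Symbols came from the reference gene table of GRCm38.p6, through accessions for 26425 probes and through the name in the file for 4814, and 24442 probes stayed unnamed and kept the name in the file. No coordinates were taken from that table. Several probes stood for 7591 features.

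The share of probes well above background lay between 52.1% in naive replicate 3 and 70.3% in naive replicate 2, and the number of arrays limits the precision. Where a gene was well above background on no array of the dimmer group, the change is given as "at least N-fold": the mean of the brighter group against the mean, over the dimmer group's arrays, of the lowest signal well above background or the gene's own signal, whichever was higher. The fitted log2 changes and their adjusted p are given for such genes too, and are not bounds.

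Groups came from the labels. The 3 comparisons were TIL against AdP1A, TIL against naive and AdP1A against naive, each tested with limma 3.58.1 (lmFit, a contrast and eBayes, two-sided) in R 4.3.3 on all 10 arrays, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Genes at a level in TIL apart from both other groups passed in both TIL comparisons with the same sign. The 18 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and 11 lists of markers of other cell types were only counted. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took a panel of 20 genes in every comparison, the 5 largest rises and 5 largest falls among passing genes with a characterised symbol, groups that did not overlap and a signal well above background on all arrays of the brighter group, and up to 2 rises and 2 falls per list. The same rule named genes apart in TIL, by the smaller change. Values of 3 genes that this rule names are not reported here, and they stay in the counts of features and of list members.

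The labels do not state that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The arrays lay on 3 slides. Slide 1 held TIL replicate 1 and AdP1A replicate 1, slide 2 held naive replicate 3, TIL replicates 3 and 4 and AdP1A replicate 3, and slide 3 held the remaining arrays. Values with the slide as a block or within slides stand beside part of the results. Slides 1 and 2 were scanned on the same day and slide 3 on another, per the file headers, so the slide as a block also covers the scan day.

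Alternatives covered normexp background correction (offset 50), quantile normalization, both together, the 75th percentile over probes detected on all arrays, the deposited log2 table, no filter, a filter on all arrays, the mean of a gene's probes, the slide or the replicate number as a block, fits of only the groups compared, a variance trend with robust fitting, leaving out each array, stricter thresholds, and list tests with an estimated correlation or with fry. A centring on sensory receptor genes was added after the data were seen.

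The fit was tested on simulated data made by shuffling each gene's residuals over the 10 arrays, on 27378 features, with 50 genes changed in TIL at each of 4 sizes. In TIL against AdP1A it recovered 0 of 50 genes changed 2-fold, 2 changed 4-fold, 26 changed 16-fold and 35 changed 256-fold, and called 4 unchanged genes. In TIL against naive it recovered 0, 2, 26 and 36 of 50 at those sizes. With no change at all, 20 simulations called at most 1 gene in any comparison, and none called a gene apart in TIL. A simulated list of random members moved by 2 (log2) was called, and no other of the 18 lists was. Each gene was shuffled on its own, which removes deviations shared between genes and unequal spread between groups. The simulations therefore do not show how often the real arrays give false calls. Few genes were changed, so the adjustment was stricter than in the real TIL against AdP1A comparison. There 2702 features passed, and the smallest called change was 1.16 (log2). The recovered shares therefore do not carry over to that comparison. Splits of the real arrays are given below. Figures were drawn with matplotlib 3.10.9.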

Results

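The series asked how CD8 T cells in a tumour differ from naive cells and from effector cells raised by an infection. Naive cells (3 arrays) were CD44-negative CD8 T cells from lymph nodes of TCRP1A mice, whose T cells carry a transgenic receptor for the tumour antigen P1A. AdP1A cells (3 arrays) were TCRP1A cells transferred into other mice and sorted as CD44-positive cells from draining lymph nodes 4 days after infection with an adenovirus coding for P1A. TIL (4 arrays) were CD3-positive CD8-positive cells from pooled melanomas of TiRP mice, sorted without a CD44 gate. The sex of the animals also differed between TIL and AdP1A, so differences between these groups cannot be told apart from it. Naive samples were labelled female, and the main probe of the sex-linked Xist was at 2.94, 1.27 and -5.19 on naive replicates 1 to 3. On TIL replicates 1 to 4 it was at -5.73, -0.55, -5.92 and -6.21. Differences between TIL and naive may therefore come from sex as well, which was not tested. Within groups the arrays correlated at 0.88 to 0.92 in AdP1A, 0.78 to 0.82 in naive and 0.77 to 0.78 in TIL, across genes, which are not independent replicates. In TIL, 26.7% of the features were well above background on some but not all 4 arrays. The share was 25.4% in naive and 16.7% in AdP1A, each over 3 arrays. Such a share tends to be larger with more arrays, so that of TIL is not directly comparable.

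TIL were set against AdP1A to compare cells from a tumour with effector cells from an infection. Cell cycle genes were lower in TIL: 17 of 27 measured members fell, and over the list alone 20 fell and 1 rose, with a median log2 difference of -4.17, or -3.47 with undetected genes at their bound (adjusted p = 5.1e-19, and adjusted p = 0.013 with an estimated correlation). Mcm2, a subunit of the replicative helicase, was at least 69.3-fold lower, and Tpx2, a spindle assembly factor, fell by 7.44 ± 0.60 (SE) on the log2 scale. The proliferation marker Mki67 differed by -6.39 ± 1.99 without passing (adjusted p = 0.0665). By fitted change, the 5 largest falls among genes with a characterised symbol were Ipo5 (at least 167-fold), Mrpl18 (at least 167-fold), Mthfd1l (at least 252-fold), Mthfd1 (at least 147-fold) and Utp14a (at least 148-fold). Mthfd1 and Mthfd1l are enzymes of folate metabolism. The median of the cell cycle list was -4.26 with the slide as a block and -4.29, -4.17 and -3.24 within slides 1, 2 and 3.

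Metabolic lists were lower in TIL too. Of 17 oxidative phosphorylation genes 6 fell, 7 over the list alone (median -3.50, or -2.93 with undetected genes at their bound, adjusted p = 4.5e-08, and adjusted p = 0.027 with an estimated correlation), among them Cycs by 6.45 ± 1.62 and Atp5b by 5.19 ± 1.23. Of 16 cholesterol and fatty acid synthesis genes 4 fell, 5 over the list alone (median -2.07, adjusted p = 5.1e-05, and adjusted p = 0.029 with an estimated correlation), with Scd2 down by 7.46 ± 1.28 and Lss at least 25.3-fold lower. Of 13 unfolded protein response genes 3 fell and none rose, 4 and 1 over the list alone (median -1.73, adjusted p = 0.0025, and adjusted p = 0.039 with an estimated correlation): Sdf2l1 fell by 4.73 ± 0.38, Pdia4 by 4.37 ± 1.19, and Pdia6 passed as well. Of 17 glycolysis genes Pgam1 and Eno1 fell, 3 over the list alone (median -1.86, adjusted p = 0.00011, lost at adjusted p = 0.066 with an estimated correlation). With the slide as a block these medians were -3.51, -2.10, -1.96 and -1.88, in that order, and Cycs (-6.52 at adjusted p = 0.0757), Atp5b (-4.85 at 0.0599), Pdia4 (-4.31 at 0.0833) and Eno1 (-2.61 at 0.059) kept a similar change without passing. Leaving out each array in turn, Cycs and Pdia4 stayed called in 2 of 10 fits, Atp5b in 6 and Eno1 in 7. Within slides 1, 2 and 3 they were -3.47, -3.25 and -3.27 for oxidative phosphorylation, -2.57, -2.08 and -2.82 for cholesterol and fatty acid synthesis, -2.49, -0.89 and -0.18 for the unfolded protein response, and -3.34, -1.11 and -1.09 for glycolysis.

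Immediate early and heat shock genes were higher in TIL: 5 of 17 rose (Hspa1a, Dusp1, Fosb, Jun and Zfp36), 6 over the list alone, with a median of 2.05 (adjusted p = 0.0043, and adjusted p = 0.039 with an estimated correlation). The median was 2.21 with the slide as a block and 2.73, 2.29 and 1.49 within slides 1, 2 and 3. The call was lost among probes detected on all arrays (adjusted p = 0.0816), and the median was 1.18 with the arrays centred on sensory receptor genes, described below with the counts. Hspa1a, an inducible heat shock protein, stood at 4.74 ± 0.37 (SD, n = 4) in TIL and -2.31 ± 0.39 (SD, n = 3) in AdP1A, a 133-fold rise. Further large rises were Nr4a2 (194-fold), Rgs1 (120-fold), Tnfaip3 (at least 25.7-fold) and Gch1 (at least 14.3-fold). Nr4a2, an orphan nuclear receptor, was at -1.36 in TIL replicate 3 and at 4.38 or more in the other TIL arrays. Nr4a2 and Gch1 did not pass with the slide as a block (7.999 at adjusted p = 0.0651, and 5.45 at 0.0722), and with Dusp1 did not pass when centred on sensory receptor genes (6.73, 4.82 and 4.79 at adjusted p = 0.0721, 0.0579 and 0.0864). They stayed called in 3, 4 and 3 of 10 fits leaving out 1 array. Ccl5, a chemokine, rose by 5.08 ± 0.55 and was the only one of 12 cytokine and chemokine genes to pass.

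Among the panel genes, granzyme B (Gzmb) fell by 2.25 ± 0.59 (adjusted p = 0.0458), the inhibitory receptor Havcr2 fell by 3.55 ± 0.86 (adjusted p = 0.0376), and Prdm1 rose by 1.38 ± 0.35 (adjusted p = 0.0434). With the slide as a block Gzmb and Prdm1 were no longer called (-2.30 at adjusted p = 0.0841, and 1.34 at adjusted p = 0.0942), while Havcr2 was (-3.78 at adjusted p = 0.0145). Centred on sensory receptor genes, Prdm1 differed by 0.52 (adjusted p = 0.394). Leaving out each array in turn, Gzmb stayed called in 2 of 10 fits, Prdm1 in 3 and Havcr2 in 4, and without any 1 AdP1A array none of the 3 was called (Gzmb at adjusted p = 0.143, 0.0835 and 0.149 without replicates 1 to 3). The other 17 did not pass. Maf, a transcription factor studied in exhaustion, differed by 3.98 ± 1.60 (adjusted p = 0.116), and 3 of 4 TIL arrays were well above background for it. The differences were 0.15 for Pdcd1, -0.16 for Tigit, -1.98 for Lag3, 1.60 for Ctla4, 2.56 for Entpd1, 2.06 for Tox, 0.16 for Eomes and 0.12 for Tbx21. They were -3.08 for Tcf7, -0.52 for Prf1, 0.37 for Ifng, 1.55 for Il2, 1.22 for Ccr7 and 3.26 for Il7r. Of 13 inhibitory receptors 2 rose (Cd101 and Cd244a) and 2 fell (Btla and Havcr2), and the list was not called (adjusted p = 0.65). Cd101, Cd244a and Btla did not pass with the slide as a block, and Cd101 and Cd244a did not when centred (2.11 and 0.60 at adjusted p = 0.159 and 0.253). Of 16 exhaustion-linked transcription factors 4 rose (Nr4a2, Nr4a3, Ikzf2 and Prdm1), 6 over the list alone, without a call for the list (adjusted p = 0.23). The transcription factor list was called higher without TIL replicate 2 (adjusted p = 0.0217), centred on sensory receptor genes (0.0231) and with fry. The inhibitory receptor list had a positive median of 0.16 and a downward test.

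The remaining lists were not called in this comparison with the planned main choices. Naive and memory genes came near (downward, adjusted p = 0.0763) and were called lower with the slide as a block (0.0436), without a filter (0.0395), without AdP1A replicate 2 (0.0237) and without TIL replicate 3 (0.0046). Interferon and migration genes were called higher with normexp (0.0449 and 0.0392), centred on sensory receptor genes (0.0218 and 0.0231) and with fry. Effector and memory genes were called lower with the mean of all probes (0.0475), and fry also called the cytokine and TGF-beta lists. Cytotoxic molecules had Fasl higher and Gzmb lower among 12 genes (median 0.28, with a downward test). Of 20 naive and memory genes the survival factor Bcl2 rose 3.43-fold and Dapl1 fell by 5.80 ± 1.33 on the log2 scale. Il2ra, a subunit of the interleukin 2 receptor, was at least 11.4-fold lower among 13 effector and memory genes. Rgs1 and Cd69 rose among 16 migration and residency genes, 6 over the list alone, with Cd69 up 11.1-fold. Of 21 interferon response genes Ifit1 and Ifit3 rose, 49.6-fold and 48.9-fold, and 3 passed over the list alone. Car9 rose 2.56-fold among 14 hypoxia genes, where the median was 0.49 and the test downward. Fasl, Bcl2, Cd69, Car9 and Ifit1 did not pass with the slide as a block (log2 1.57, 1.85, 3.41, 1.36 and 5.31, at adjusted p = 0.0521 to 0.0916). They did not pass when centred on sensory receptor genes either (0.67, 0.91, 2.60, 0.49 and 4.77), nor did Ifit3 (4.75), and Bcl2 stayed called in 4 of 10 fits leaving out 1 array. No member passed among 8 costimulatory receptors, 18 genes of the TCR complex and its signalling (median 0.17, with a downward test) and 13 genes of TGF-beta signalling.

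In all, limma called 1451 features higher and 1251 lower in TIL than in AdP1A. The split varied with the scaling, the probe filter and the arrays used. The median of all features was 0.58 higher in TIL than in AdP1A, and 660 olfactory, vomeronasal and taste receptor genes were 0.97 higher in the median. With arrays centred on those receptor genes, a choice made after the data were seen and one that lowers every TIL minus AdP1A difference by about the same amount, 92 features were higher and 2045 lower. With the percentile over probes detected on all arrays the split was 566 higher and 1263 lower, and with normexp it was 568 and 970. It was 1843 and 1361 with quantile normalization, 1858 and 1608 with normexp and quantile, and 1881 and 1358 in the deposited log2 values. Among probes detected on all arrays it was 2502 and 650, with a variance trend 1975 and 1329, and in a fit of these groups alone 573 and 1219. With the slide as a block 976 features passed, 233 higher and 743 lower. Of the 2702 called features 2700 had the same sign within every slide. That is no separate support, since the features were called on the same arrays. Without AdP1A replicate 1, 2 or 3, 553, 1121 or 525 passed (60, 345 or 49 of them higher), and without TIL replicate 1, 2 or 3, 1359, 1242 or 1629. Of the 46 called genes named by rule and reported here, 23 stayed called with the slide as a block and 13 under every alternative that gave a value, among them Hspa1a, Ccl5, Mcm2, Tpx2, Sdf2l1, Ipo5, Mrpl18, Mthfd1l and Utp14a.

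**Figure D1:**
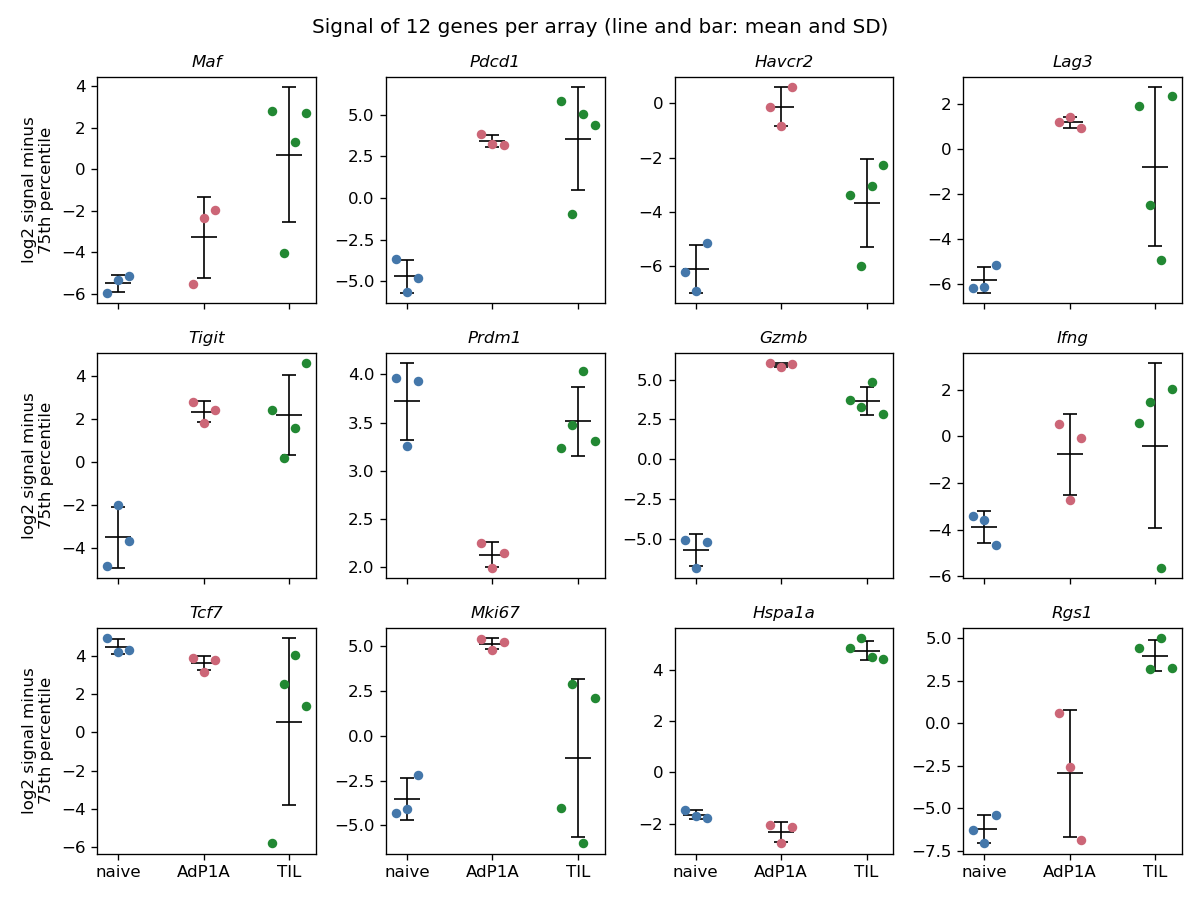
Log2 signal minus the 75th percentile of the array for 12 genes, with 1 point per array, grouped as naive (n = 3), AdP1A (n = 3) and TIL (n = 4); lines and bars show mean and SD. Hspa1a lies at 4.74 in the TIL mean and at -2.31 in the AdP1A mean, and Maf has an SD of 3.24 over the TIL arrays.

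TIL were set against naive cells to find what separates CD8 T cells in a tumour from cells that had not met antigen. Gzmb was at least 204-fold higher in TIL (adjusted p = 0.000332), Rgs1, a regulator of G protein signalling, at least 247-fold, Lilr4b at least 116-fold and Bcl2a1d at least 36.5-fold. S100a4 rose 183-fold, from -1.46 ± 1.19 (SD, n = 3) to 6.06 ± 0.42 (SD, n = 4). By fitted change, the largest falls among genes with a characterised symbol were Mthfd1l (at least 119-fold), Utp14a (at least 64.2-fold), Ears2 (at least 61.3-fold), Slc43a2 (at least 32.5-fold) and Kcnmb1 (at least 31.9-fold). Rgs1, Lilr4b, Bcl2a1d, Utp14a, Slc43a2 and Kcnmb1 did not pass with the slide as a block (log2 9.55, 7.32, 7.37, -8.50, -6.81 and -7.02, at adjusted p = 0.0626 to 0.124), while Gzmb, S100a4, Mthfd1l and Ears2 did. Leaving out each array in turn, Rgs1 stayed called in 3 of 10 fits and the others of these genes in at least 8.

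Of 18 lists 10 were called, 9 of them higher in TIL. Immediate early and heat shock genes had a median of 2.86 (adjusted p = 3e-13, and adjusted p = 0.0013 with an estimated correlation): Hspa1a rose by 6.38 ± 0.36 and Zfp36 by 4.34 ± 0.61, and 11 of 17 passed over the list alone. Naive and memory genes had a median of -2.14 (adjusted p = 1.6e-10, and adjusted p = 0.023 with an estimated correlation), with no member passing over all features and 5 of 20 lower over the list alone. Migration and residency genes had a median of 2.00, with 3 of 16 passing, Rgs1 and Itgb1 among them (adjusted p = 0.012 with an estimated correlation). Inhibitory receptors had a median of 2.42, or 0.92 with undetected genes at their bound, and no member passed over all features while 3 of 13 rose over the list alone (adjusted p = 0.031 with an estimated correlation). Exhaustion-linked transcription factors (median 1.54, 5 of 16 over the list alone), cytotoxic molecules (median 1.25, Gzmb alone passing) and cytokines and chemokines (median 3.16, or 2.00 with undetected genes at their bound and 1.82 and 1.85 within slides 2 and 3, Ccl5 alone passing) were called with adjusted p = 0.014, 0.031 and 0.031 with an estimated correlation. Calls for effector genes, glycolysis and the interferon response were lost at adjusted p = 0.1, 0.26 and 0.073 with an estimated correlation. Zfp36 and Ccl5 did not pass with the slide as a block (4.46 and 3.61 at adjusted p = 0.143 and 0.147) and stayed called in 4 of 10 fits leaving out 1 array. The call for inhibitory receptors was also lost among probes detected on all arrays (adjusted p = 0.203). Costimulatory receptors, TCR signalling, cell cycle, oxidative phosphorylation, cholesterol synthesis, hypoxia, unfolded protein and TGF-beta lists were not called and had no passing member. Of these, cholesterol synthesis was called higher with normexp and quantile (adjusted p = 0.043), without TIL replicate 2 (0.0255) and without naive replicate 1 (0.0482). Within slides 2 and 3 the medians were 3.20 and 2.59 for immediate early and heat shock genes, -1.25 and -2.69 for naive and memory genes, and 2.51 and 0.57 for inhibitory receptors.

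Of the panel only Gzmb passed. Pdcd1 was well above background on all 4 TIL arrays and on no naive array, at least 174-fold apart, with adjusted p = 0.0671, and Eomes and Tigit differed by 5.46 and 5.72 with adjusted p = 0.0784 each. Maf differed by 6.18 (adjusted p = 0.268), Lag3 by 5.01, Ctla4 by 3.11, Havcr2 by 2.42, Ifng by 3.49, Mki67 by 2.27, Tbx21 by 1.35, Il7r by 1.13, Tox by 1.04 and Entpd1 by 0.89. Differences below 0 were -3.92 for Tcf7, -1.51 for Ccr7, -0.69 for Il2, -0.33 for Prf1 and -0.20 for Prdm1. The fit called 32 features higher and 44 lower, and 2268 had an unadjusted p under 0.05. With the slide as a block 18 passed, with probes detected on all arrays 23, and in a fit of these groups alone 30. Without AdP1A replicate 2 or 3, which enter only through the shared spread, 46 or 50 passed, and without TIL replicate 2, 127. All 76 had the same sign within slides 2 and 3, which is no separate support, since they were called on the same arrays.

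AdP1A were set against naive cells for the changes of a response to infection. Cell cycle genes were higher: 18 of 27 rose, 22 over the list alone (median 3.91, adjusted p = 1.9e-20, and adjusted p = 0.011 with an estimated correlation), with Mki67 403-fold and Top2a at least 201-fold up. Gzmb was at least 965-fold higher, and Stmn1 (at least 445-fold), Mrpl18 (at least 168-fold) and Gpr55 (at least 163-fold) were the next largest rises by fitted change. Inhibitory receptors rose in 4 of 13 members, Pdcd1 (at least 157-fold), Lag3 (at least 35.9-fold), Havcr2 (at least 14.7-fold) and Tigit (58.6-fold), while Cd244a fell. The list's call was lost at adjusted p = 0.12 with an estimated correlation and at adjusted p = 0.813 among probes detected on all arrays. Eomes rose 39.5-fold and Batf 62.5-fold. Ccr7, a lymph node homing receptor, fell by 2.72 ± 0.46, Il2 fell by 2.24 ± 0.50 and Prdm1 fell by 1.59 ± 0.38. Over the alternatives Il2 ranged from -2.61 to -0.46 (adjusted p up to 0.553) and Prdm1 from -1.82 to -0.65 (adjusted p up to 0.322), and centred on sensory receptor genes they differed by -1.30 and -0.65 without passing, as did Cd244a (-0.66). Mki67, Pdcd1, Lag3, Tigit, Eomes, Batf, Cd244a, Il2 and Prdm1 did not pass with the slide as a block (adjusted p = 0.0626 to 0.139). Gzmb, Stmn1, Mrpl18, Gpr55, Top2a, Havcr2 and Ccr7 did.

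Glycolysis (5 of 17, median 3.04), oxidative phosphorylation (5 of 17, median 2.97), cholesterol and fatty acid synthesis (4 of 16, median 3.41) and the unfolded protein response (2 of 13, median 1.85) rose in the numbers given, with adjusted p = 0.036, 0.017, 0.017 and 0.025 with an estimated correlation. With undetected genes at their bound these medians were 2.41, 2.95, 2.99 and 1.72. Effector genes were called with Ly6c1 alone passing (adjusted p = 0.048 with an estimated correlation), and the call for cytotoxic molecules, with Gzmb, Gzma and Gzmc passing, was lost at adjusted p = 0.13 with an estimated correlation. Of the lists not called, Itgb1 rose among migration genes, Ifi35 among interferon genes and Hsp90aa1 among immediate early and heat shock genes, in which Jun fell. Migration genes (adjusted p = 0.0559) were called higher without a filter (0.0372), without AdP1A replicate 2 (0.0175) and without naive replicate 1 (0.037), and costimulatory receptors with the mean of all probes (0.0458). Foxp1, Ccr7 and Bcl2 fell among 20 naive and memory genes (median -1.57), a list just short of the threshold (adjusted p = 0.053, and adjusted p = 0.29 with an estimated correlation). It was called lower with the slide as a block (adjusted p = 0.029), normexp (0.0048), quantile normalization (0.037), both together (0.013), the deposited log2 values (0.038) and no filter (0.031). Fits of these groups alone (0.0061), fry (0.026), centring on sensory receptor genes (0.0011) and further alternatives, among them some fits leaving out 1 array, called it too. Smad4 fell among TGF-beta genes. Ly6c1, Gzma, Foxp1, Jun and Smad4 did not pass with the slide as a block (5.15, 5.16, -2.88, -2.46 and -1.98, at adjusted p = 0.0653 to 0.14), nor Foxp1 and Smad4 when centred (-2.26 and -0.99). No member passed among costimulatory, TCR signalling and hypoxia genes. Within slides 2 and 3 the cell cycle median was 4.21 and 3.35, and the other lists of this comparison are not given within slides here. Panel genes that did not pass differed by 1.23 (Tbx21), 1.51 (Ctla4), 3.12 (Ifng), 2.20 (Maf), 0.19 (Prf1), -0.85 (Tcf7), -1.03 (Tox), -1.66 (Entpd1) and -2.13 (Il7r). By fitted change, the largest falls among genes with a characterised symbol were Stard5, She, Tas2r114, Vmn2r96 and Kcnmb1; Tas2r114 and Vmn2r96 belong to the taste and vomeronasal receptor families.

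The fit called 1102 features higher and 783 lower in AdP1A. The split again varied: centred on sensory receptor genes, 2243 were higher and 90 lower, with normexp 598 and 117, with quantile normalization 1318 and 1545, with both together 1555 and 1858, and in the deposited log2 values 1331 and 1714. Among probes detected on all arrays it was 622 and 1522, and with a variance trend 1205 and 1278. With the slide as a block 555 passed, 474 higher and 81 lower. Within slides 2 and 3, 1884 of the 1885 called features had the same sign, again on the arrays that gave the calls. Without AdP1A replicate 1, 2 or 3, 502, 874 or 470 passed (69, 216 or 55 of them lower), and without naive replicate 1 or 3, 839 or 785.

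**Figure D2:**
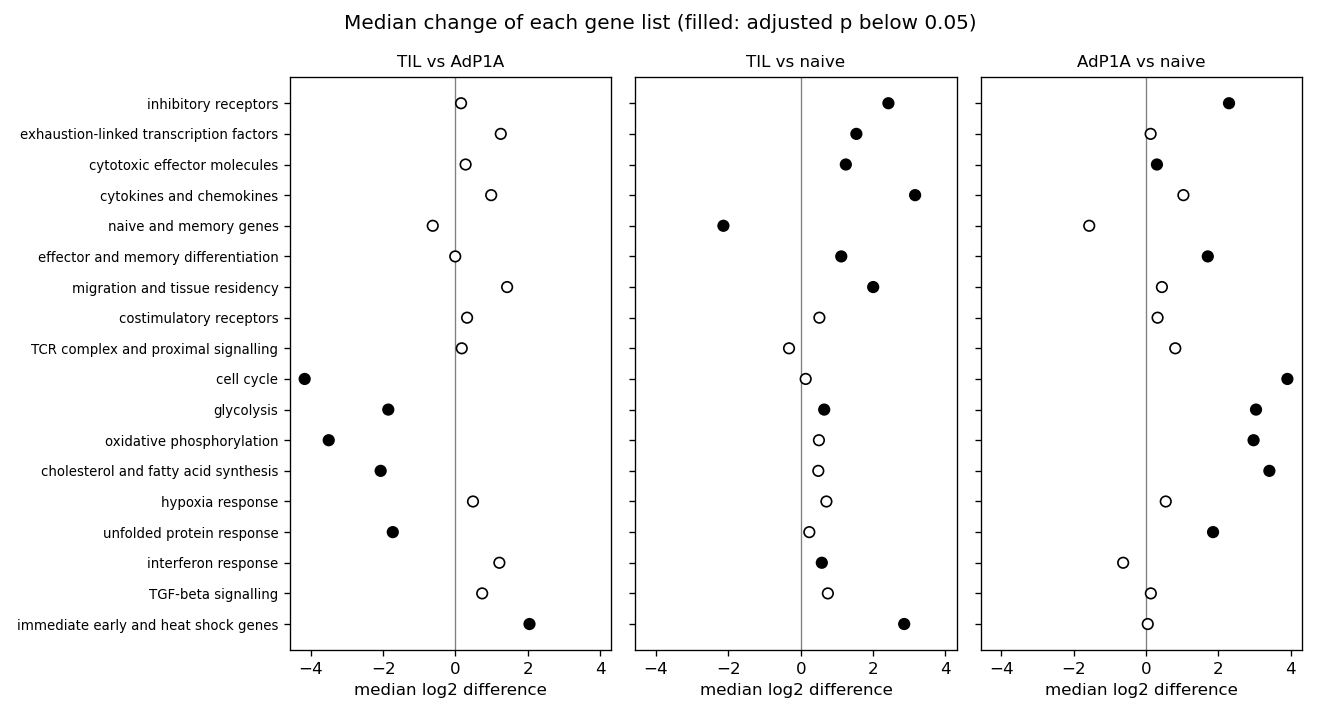
Median log2 difference of 18 gene lists in the 3 comparisons; filled points had an adjusted p below the threshold with the preset correlation. Cell cycle genes lie at -4.17 in TIL against AdP1A, 0.14 in TIL against naive (-0.01 with the slide as a block) and 3.91 in AdP1A against naive.

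Apart from both other groups, 12 features were higher and 24 lower in TIL. Higher ones with a symbol included Rgs1 (smaller change 6.90), Hspa1a (6.38), Lilr4b (4.51), Ccl5 (3.80) and Sfn (3.18), and lower ones Mthfd1l (-8.17), Utp14a (-8.02), Las1l (-6.39), Ears2 (-6.17) and Ggt1 (-5.53). Against naive, Rgs1, Lilr4b, Ccl5, Sfn and Utp14a did not pass with the slide as a block, while Hspa1a, Mthfd1l and Ears2 did. Independent lists of these sizes would share 1.69 higher and 2.01 lower features. Simulations of unchanged groups, with each gene shuffled on its own, shared 0, while regroupings of the real arrays gave up to 76. Since both comparisons use the TIL arrays, part of the excess may come from them. The sex of the animals may also enter both comparisons. With the slide as a block 12 features passed, with probes detected on all arrays 13, without AdP1A replicate 1, 2 or 3, 19, 18 or 19, and without TIL replicate 2, TIL replicate 4 or naive replicate 3, 66, 60 or 70.

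Markers of other cell types were counted in each comparison. Against AdP1A, TIL were higher for Apoe and C1qc among 14 macrophage markers, Sox10 among 10 melanocyte markers, Sfn and Krt15 among 6 keratinocyte markers, Cr2 and Cd22 among 10 B cell markers and Cd4 among 5 CD4 and regulatory markers, and lower for Il2ra and the sex-linked Xist. Of the 8 higher markers only Sfn passed with the slide as a block, where the others differed by 1.32 to 4.20 (adjusted p = 0.0556 to 0.0945), or when centred on sensory receptor genes, where they differed by 0.48 to 3.30 (adjusted p = 0.0517 to 0.392). Cd22 differed by as little as 0.053 over the alternatives. Against naive, TIL were higher for Sfn and lower for Pmel, and in AdP1A against naive, Pmel, Fcer2a and Krt15 were lower, none of these passing with the slide as a block. Dendritic, NK, neutrophil, red cell and stromal lists had no passing member in any comparison.

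Probes for segments of the T cell receptor were examined after their values were seen. Of 120 annotated receptor probes, 12 had naive and AdP1A means above 4, and their median per array was 6.62 to 7.21 in naive, 6.37 to 6.73 in AdP1A and -2.86 to 1.75 in TIL. Of these 12, the probes at chr6:41497058-41497622, chr6:41489287-41489346 and chr14:54841807-54842701 (mm9, the build of the array's annotation) differed by -1.08, -0.67 and -1.40 between TIL and naive. The remaining probes differed by -5.26 to -10.11.

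**Figure D3:**
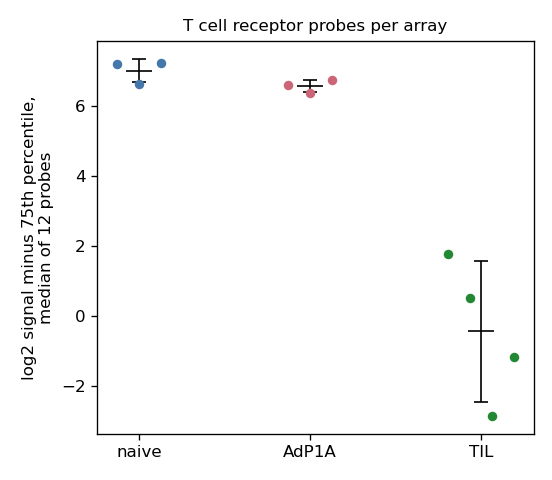
Median log2 signal, minus the 75th percentile of the array, of 12 T cell receptor probes on each array, grouped as naive (n = 3), AdP1A (n = 3) and TIL (n = 4); points are arrays, and lines and bars show mean and SD. The TIL arrays lie between -2.86 and 1.75, below all naive and AdP1A arrays.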

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

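Of the tests given here, that of independent loss was chosen before its result was seen, and the tests of scaling, detection, the dividing state of AdP1A, handling, macrophages and sex, and the splits of the arrays, after it. In 7 of 110 tested sets of 4 TIL values, 6.36%, 1 array stood far from the others, where chance gives about 1 in 20. Entpd1 was at 2.89 in TIL replicate 3 and at -3.89 to -3.62 in the others. Nr4a2 was at -1.36 in TIL replicate 3 and at 4.38 to 4.74 in the others. Fasl was at 1.49 in TIL replicate 4 and at 1.27 to 1.30 in the others. In TIL replicate 2, Apoe was at 1.93 (others 3.59 to 3.84), Xist at -0.55 (others -6.21 to -5.73) and the median of inhibitory receptors at -0.97 (others 1.57 to 2.07). The median of cell cycle genes was at -0.49 in TIL replicate 4 and at -2.19 to -1.92 in the others.

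Among the 1251 features lower in TIL than in AdP1A, independent loss of transcripts on each TIL array is argued against only for the 379 detected on no TIL array. Of 21477 features detected on all AdP1A arrays, 472 were detected on no TIL array where 1.94 were expected, a ratio of 243.6. For the 418 lower features detected on some TIL arrays independent loss was not tested. Loss that favours the same transcripts on all arrays was not tested either. Scaling as the whole cause is argued against for the 1251 lower features: their median fall was 4.39 (log2), the median difference of all features moved by 0.87 over 7 scalings, and 91.4% of the lower features were still called lower with the TIL arrays raised by that much. The share of detected probes overlapped (58.2, 60.6, 59.6 and 63.8% on TIL arrays, 60.3, 63.6 and 64.7% on AdP1A arrays), though 2 TIL arrays lay below every AdP1A array. Of the lower features, 454 (36.3%) were well above background on all 4 TIL arrays, too few to decide on lower detection as the cause. It cannot be told apart from a lower level for the 418 and 379 features well above background on some or none of the TIL arrays. At least 89.0% of the features called lower without 1 AdP1A array had a naive mean below that left-out array, against at most 37.6% of all features. Most of these features were thus high in AdP1A against naive as well. A general state of dividing AdP1A cells remains a candidate explanation. The share cannot decide on it, because any rise particular to the AdP1A arrays would give it too. The tissue and the sex of the animals, which differ between the groups, stay open and untested. The main Xist probe was at -5.73, -0.55, -5.92 and -6.21 on TIL replicates 1 to 4, and at 2.96, 2.43 and 2.58 on AdP1A replicates 1 to 3.

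Immediate early and heat shock genes were 2.86 higher (log2, median) in TIL than in naive. Handling of the tumours before the sort may account for this and cannot be told apart from a state in the tumour, because only TIL came from tumours and went through ficoll. Macrophages in the TIL samples, which the CD3 and CD8 gate would remove, cannot be told apart either. None of 14 markers passed, and 3 rose by at least 2.86 (Ctss by 5.08, Fcer1g by 4.69, C1qc by 3.06). Smaller rises were 2.31 for Apoe, 2.22 for C1qb, 1.51 for Tyrobp, 0.998 for C1qa, 0.56 for Adgre1 and 0.45 for Cd14. Itgam, Csf1r, Lyz2, Cd68 and Fcgr1 differed by 0.056, 0.17, -0.56, -0.06 and -0.18. Of these, Itgam and Csf1r were already bright in naive cells (means 8.75 and 5.005).

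Naive replicate 3, labelled female like its group, had Xist at -5.19 where naive replicates 1 and 2 had 2.94 and 1.27, while a second Xist probe was well above background there at -2.35, against -0.99 and 1.89. Loss of Xist in the amplification cannot be told apart from other causes: Eif2s3y, a Y-linked gene, lay 4.59 above the highest other naive or AdP1A array, but ranged over 7.34 within the TIL arrays (-2.79, -3.25, 4.09 and -3.11). A swap with a TIL array is argued against by the receptor probes, whose median lay 7.35 farther from the TIL mean than from the other naive arrays. Male cells in this sample may account for it but cannot be told apart from other causes, because 0 Y-linked genes were detected there and on no other naive or AdP1A array, Eif2s3y was detected in both groups, and the others lay near the floor.

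Other splits of the arrays were drawn for the counts. They do not address the tissue or the sex of the animals, which differ between the groups. For TIL against AdP1A, only the real one of 35 splits gave as many as the 2702 genes (highest other 372). For the 6 lists, 11 of 35 splits, the real one included, gave as many (highest other 9). For TIL against naive, only the real one of 35 splits was as large for the 76 genes (highest other 75). The same held for the 10 lists (highest other 9), so the margin was 1 gene and 1 list. That margin is smaller than the changes between settings, with 18 genes with the slide as a block, 46 without AdP1A replicate 2 and 7 lists without TIL replicate 3, so little can be built on it. The split with 75 genes put TIL replicate 2 among the naive arrays. For AdP1A against naive the 10 splits are too few for a share under 0.05 (1885 genes, highest other 9; 8 lists, highest other 9, 3 splits as large). For the 36 features apart in TIL, 3 of 100 splits, the real one included, gave as many, and the 2 others (76 and 61) set the AdP1A arrays with 1 other array apart, a structure of the samples.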

How the results depend on the processing

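The centring on sensory receptor genes and the list medians under quantile scalings were chosen after the data were seen; the other alternatives were planned. Where no cause is named it was not tested. Stricter thresholds lower counts by construction, fewer arrays or fewer probes gave lower or higher counts, and dim signal limits genes near background. Against 2702, 76, 1885 and 36 genes (TIL vs AdP1A, TIL vs naive, AdP1A vs naive, TIL apart), the slide as a block gave 976, 18, 555 and 12, and adjusted p under 0.01 gave 451, 20, 395 and 10. Same-numbered samples deviated together by r = -0.04 to 0.09 across genes, so the numbers did not pair them; the replicate number as a block gave 1120, 36, 842 and 21. Normexp gave 1538 and 715 for TIL vs AdP1A and AdP1A vs naive. For AdP1A vs naive, quantile normalization gave 2863, normexp with quantile 3413 and the table of the authors gave 3045. Probes detected on all arrays gave 23 (TIL vs naive) and 13 (TIL apart), and fits of the compared groups alone 1792 (TIL vs AdP1A) and 30 (TIL vs naive). Fry called 11 lists in TIL vs AdP1A against 6. Counts under the other alternatives were within 1.5 times. Leaving out each array gave 525 to 3935, 46 to 127, 470 to 1918 and 18 to 70 genes, and 6 to 7, 7 to 11 and 8 to 9 lists. Of 145 named values 12 changed sign somewhere, none of them called. For TIL vs AdP1A, Tigit became 0.10 with normexp and 0.077 with normexp and quantile; with the percentile over detected probes Tbx21 became -0.17, Eomes -0.13 and Pdcd1 -0.13; with the replicate block Eomes -0.45, Pdcd1 -0.12 and Ifng -0.44; centred on sensory receptor genes Tbx21 -0.75, Eomes -0.71, Pdcd1 -0.71 and Ifng -0.50. For TIL vs naive, Prdm1 became 0.068 with normexp, Il7r -0.33 with the slide block and Prf1 0.030 with the replicate block. For AdP1A vs naive, Prf1 became -0.11 and Tcf7 0.50 with the slide block, and Tcf7 became 0.087 when centred. Leaving out each array, TIL vs AdP1A ranged over -0.44 to 0.64 for Tbx21, -0.45 to 0.80 for Eomes, -0.59 to 1.66 for Pdcd1, -0.97 to 0.52 for Tigit and -0.62 to 2.11 for Ifng. TIL vs naive ranged over -1.21 to 0.84 for Prf1, -0.76 to 1.503 for Entpd1 and -0.52 to 3.48 for Il7r, and AdP1A vs naive over -0.68 to 1.37 for Prf1 and -3.49 to 0.23 for Il7r. No median of a called list changed sign, and 33 of 270 list medians moved by more than the spread between replicates. Of called named genes, 13 of 46, 4 of 16 and 13 of 40 stayed called under every alternative that gave them a value; among probes detected on all arrays 19, 6 and 16 had one.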

Other observations

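The tests in this part were chosen after the results were seen. Of 120 annotated T cell receptor probes, 42 lay more than 2 (log2) above all naive and AdP1A arrays on at least 1 TIL array, 25 of them in TIL replicate 1, 14 in replicate 2, 17 in replicate 3 and 19 in replicate 4. The same count was not made for other probes, so whether this share is particular to receptor probes stays open. A probe for M54990, a receptor gamma chain sequence, was higher in TIL than in both other groups, by at least 6.23.

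A hypothesis for the receptor probes is that those bright in naive and AdP1A cells detect the transgenic receptor of TCRP1A mice, which cells in TiRP tumours may lack. It needs naive and AdP1A to be close and TIL far below: for probes chosen on the AdP1A mean alone, which gave the same 12, the medians differed by -0.44 between AdP1A and naive, and the highest TIL array lay 4.87 below the lowest naive array. For 2578 other probes chosen so, it lay 1.27 above it. The values go with the hypothesis, which was found and tested on the same arrays. The receptor of TIL is not given by the labels, and the sequences recognised by the 3 probes that stayed bright were not examined.

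A hypothesis for features higher in TIL than in AdP1A is a general shift of the AdP1A arrays against both other groups, shared by genes with no known use in T cells. The 660 sensory receptor genes differed by 0.97 between TIL and AdP1A, 0.04 between TIL and naive and -0.98 between AdP1A and naive (median log2), and 5.91% of them were called higher in TIL than in AdP1A, near the 5.29% of all features. The lowest naive or TIL array lay 0.50 above the highest AdP1A array in the median of these genes. Of the features called higher without 1 AdP1A array (60, 345 or 49), at least 88.1% had a naive mean above that left-out array, against at most 64.6% of all features. Centred on these genes 92 features were higher, against 1451, but that centring lowers every TIL minus AdP1A difference alike, so how many calls the shift may account for stays open. The 20 brightest features also had lower means in AdP1A than in both other groups. The brightest, Dennd4a, was at 9.36 in AdP1A, 10.34 in TIL and 10.58 in naive. Before scaling, the 75th percentile of the processed signal was 737, 535 and 702 on AdP1A replicates 1 to 3. It was 344, 253, 255 and 550 on TIL replicates 1 to 4, and 300, 466 and 261 on naive replicates 1 to 3. Whether the shift came from the scaling, the amplification, the labelling or the RNA content of dividing cells was not tested.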
